A study of Scophthalmus maximus with 21 samples.

How the data were processed

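DNA methylation was measured by reduced representation bisulfite sequencing, in which genomic DNA is cut at CCGG sites and unmethylated cytosines are read as thymines. The tissue was the eye of turbot (Scophthalmus maximus), a flatfish whose right eye moves across the head at metamorphosis. The 21 libraries fall into 6 groups. The left (non-migrant) eye had 3 libraries at 13 days post fertilization (dpf), 4 at 21 dpf and 4 at 44 dpf, and the right (migrant) eye had 2, 4 and 4. The pre-metamorphic, climax and post-metamorphic stages of the study's design were taken as 13, 21 and 44 dpf in order of age, since the labels give days only. The labels do not say whether the samples come from separate animals, so p-values measure the spread between these samples. Tests of stages over both eyes, of regions and of library values, take left and right eye libraries as independent. If pairs of them come from the same fish, those p-values can be too low.

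The authors mapped the reads with BSMAP 2.90. Its tables list every cytosine with 1 or more reads, on 22 chromosomes. The deposited columns hold raw read counts per cytosine, namely methylated (C) reads, C plus T reads, and G and G plus A reads of the opposite strand. The deposited methylation ratio is a fraction of methylated reads, corrected by the opposite strand for C/T variants, and was not used further. Trimming, duplicate handling and the genome build are not given in the sources used here. The gene table at hand does not share the coordinates of the files, since on several chromosomes its genes end beyond the last cytosine listed. No region was therefore assigned to a gene, and the planned tests of gene lists and of genomic features were not run.

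The C and C plus T reads of both strands of a CpG were summed. A CpG was used with 10 or more reads in all 21 libraries, which 173422 CpGs met. Of these, 605 were left out as C/T variants (G share of the opposite strand under 0.9 over all libraries, or under 0.75 in a library with 8 or more such reads). The libraries held 8 or more opposite strand reads together at 59.0% of the CpGs, so a variant could be seen at these alone. A further 2377 CpGs above the 99.9th percentile of depth in any library were left out, and 170440 remained. Runs of CpGs at most 100 bp apart, ended at 500 bp, gave 22547 regions of 3 or more CpGs, holding 148095 CpGs. A region had a median of 5 CpGs and of 49 bp. CpGs and regions were classed by their mean over all libraries as under 10%, 10 to 80%, or 80% or more methylated.

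Libraries held 46042259 to 89824582 base calls over CpGs, and the median depth per CpG was 16 to 46. The reads of a region were summed over its CpGs, so a read counts once for each CpG it covers. By this count the median region had 530 reads in a library, and the lowest of all libraries and regions was 30. A 95% Wilson interval is at most 26.3 percentage points wide on either side at 10 reads, and 4.24 points at a count of 530. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Over regions or whole libraries a read counts once for each cytosine it covers, so intervals are too narrow and floors too low there. The floor is the share that 3 counts would give.

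Each region was fitted with a logistic model of its methylated and unmethylated reads, with the 6 groups as the model's terms (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). Group differences were tested by a quasi-binomial likelihood ratio F test, whose dispersion was estimated over all 21 libraries, moderated by empirical Bayes and never below 1. P-values were adjusted by Benjamini-Hochberg within each of the 12 comparisons. A region was called at an adjusted p under 0.05 and a difference of at least 10 percentage points. The difference, and so the direction and size of a call, is that of the group means of library methylation. It stays so with edgeR, limma, a block or a further term, which change the p-value alone. For stages over both eyes, the difference is the mean of the differences in each eye. Library values were compared by two-sided exact permutation tests (stage labels permuted within eye, eye labels within stage), adjusted by Benjamini-Hochberg over 6 comparisons of each measure. Data were simulated with the spread of regions in these libraries, each region and library drawn independently. In them, 88% of regions changed by 40 points and 49% of those changed by 20 points were called between 44 and 13 dpf. For the eyes, 73 to 79% of regions changed by 40 points were called. With 100 regions changed by each of these amounts, 4.86% of the calls between 44 and 13 dpf were false (7 calls), and 19.5% (26), 10.2% (13) and 7.32% (9) of those for the eyes at 13, 21 and 44 dpf. With no region changed, 40 simulations gave 0 or 1 call between 44 and 13 dpf and 6 to 31 for the eyes at 13 dpf (median 17.5). Their unadjusted p was under 0.05 in 6.86% and 9.8% of regions, so the test is too lenient in both. These 40 simulations were chosen after seeing the data. No simulation holds a shift shared by the regions of a whole library, so calls that arise without a change can be understated.

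The named regions were chosen by a rule fixed before the data were examined, as were the tests, thresholds and filters above. The rule takes, from the called regions whose libraries do not overlap between the 2 groups, the 6 with the largest rise and the 6 with the largest fall. Where none was called, the 3 of lowest p are named. The rule had been written for genes and was applied to regions by position.

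The variations set down beforehand were a coverage minimum of 5 or 20 reads, no variant filter, edgeR 4.0.16 in place of the logistic model (R 4.3.3), single CpGs, only the libraries of the groups compared, a difference of 25 points, the replicate number as a block, library numbers 11 apart as a block for the eyes, and each library left out in turn. The share of methylated reads was tried in place of the mean over CpGs. Others were chosen after seeing the data. These were limma 3.58.1 with equal weights, a rule of 10 reads in at least 2 libraries per group, and leaving out the 2 libraries of highest non-CpG methylation. The last were 2 terms for the libraries themselves. One term is the depth ratio, the log2 of a library's mean depth at CpGs of 80% or more over that at CpGs under 10%. The other is the library set, 1 of 4 sets found by hierarchical clustering of 2 measures of the CHG and CHH cytosines, taken without CpG values. The first measure was the percentage of methylated reads at cytosines under 50%. The second was the share of cytosines within 25 bp of one of 50% or more that were of 50% or more themselves. For library values, the effect of either term was estimated once within the real groups and taken out before labels were permuted. It was not fitted anew for each permutation, so those p-values can be too low.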

Results

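Eyes of turbot were profiled at 3 ages that span metamorphosis, when the right eye migrates to the left side of the head. The series title concerns how DNA methylation changes while the visual system is remodelled. Its design sets the migrating eye against the other eye, and the stages against each other. Of the 21 libraries, 5 were taken at 13 dpf (3 left, 2 right), 8 at 21 dpf and 8 at 44 dpf (4 of each eye). Each library held 46042259 to 89824582 base calls over 874471 to 1975472 CpGs. Of the 170440 CpGs read 10 or more times in every library, 65.1% were under 10% methylated, 39912 were at 10 to 80%, and 19648 were at 80% or more. The regions divide in the same way, with 13167, 6568 and 2812 in these classes.

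The libraries also differed in ways that the eye and stage labels do not name. Set 1 of the 4 library sets held 4 of the 5 libraries of 13 dpf, with right eye 21 dpf replicate 2 and left eye 44 dpf replicate 1. The other 13 dpf library, left eye replicate 2, stood in set 3, with 5 libraries of 21 dpf and 2 of 44 dpf. Set 2 held 1 library of 21 dpf and 4 of 44 dpf. Set 4 held right eye 21 dpf replicate 3 and right eye 44 dpf replicate 1. The ratio of depth at highly methylated CpGs to depth at CpGs under 10% was 0.533 ± 0.280 (SD, n = 5) at 13 dpf, 0.909 ± 0.284 (n = 8) at 21 dpf and 1.02 ± 0.329 (n = 8) at 44 dpf. The difference of 0.483 between 44 and 13 dpf had an exact permutation p of 0.0267, and an adjusted p of 0.149. On the log2 scale this ratio followed the mean methylation of the 21 libraries (Pearson r = 0.972, Spearman rho = 0.906, permutation p = 1e-05 for both, the smallest that could be reached). Pearson's p was 3e-05 after adjustment over the 6 correlations computed. Without the 2 libraries farthest from the median ratio, r was 0.957. Within set 1 r was 0.967 (rho 0.943, n = 6, exact permutation p = 0.00556 and 0.0167), and within set 3 it was 0.965 (rho 0.857, n = 8, exact permutation p = 0.00057 and 0.0107). Among the 8 libraries of 21 dpf r was 0.984 (rho 0.976), with exact permutation p of 7.44e-05 and 0.000397. Among those of 44 dpf r was 0.959 (exact permutation p = 0.0132), while rho was 0.524 (p = 0.197).

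**Figure D1:**
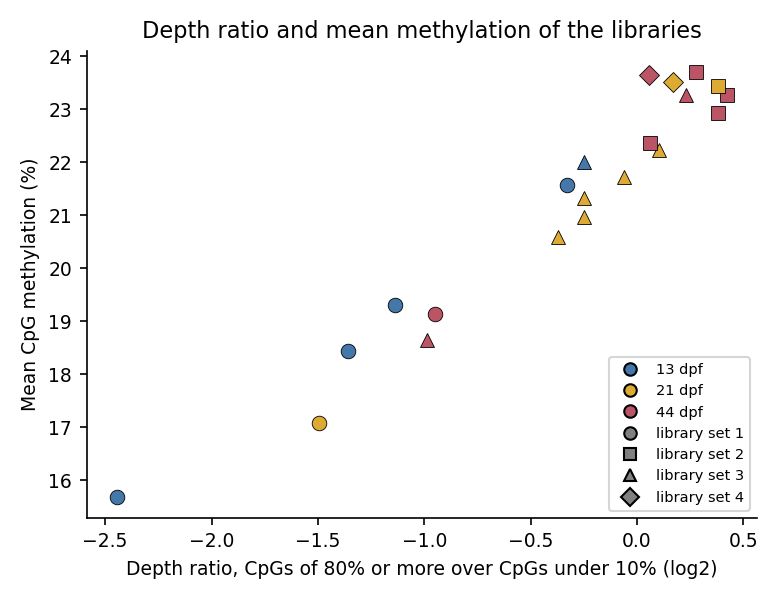
Mean CpG methylation of each of the 21 libraries (%, vertical axis) against its depth ratio (log2, horizontal axis), with the age as colour and the library set as symbol. The libraries run from 15.7% at the lowest ratio to 23.7%, and 4 of the 5 libraries of 13 dpf are circles of set 1.

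Between 13 and 44 dpf, the comparison that spans the whole of metamorphosis, the regions called with the groups alone mostly gained methylation. Those called with the depth ratio or the set as a term did not (39 higher and 43 lower, and 17 higher and 28 lower). These directions are those of the group means, not of the fit with the term. Of 22547 regions, 271 were higher and 28 lower at 44 dpf, and 250 of the 271 lay in the class of 10 to 80%. The test took left and right eye libraries as independent, which they are not if pairs of them come from the same fish. In the regions that rose, the median level went from 8.63% at 13 dpf through 24.3% at 21 dpf to 36.2% at 44 dpf. In those that fell, it went from 86.1% through 68.9% to 59.7%. Regions chosen for their difference between 13 and 44 dpf tend to lie between the 2 at 21 dpf, so this course does not show when the change took place. The median change was 21.0 points in the left eye and 29.2 in the right for the rises, and -16.0 and -22.0 points for the falls, in regions called on the mean of the 2 eyes. By edgeR 29 regions were called (25 higher, 4 lower), 21 of them as before, and by limma 188 (167 higher, 21 lower), 127 of them as before.

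Values within library sets are given for the same regions, which were called from these libraries, so their direction there is no separate test. In set 1 (4 libraries at 13 dpf, 1 at 44 dpf) 250 of the 271 rises were higher at 44 dpf, by a median of 16.9 points over all 271, and 27 of the 28 falls were lower. In set 3 (1 library at 13 dpf, 2 at 44 dpf) 245 of the 271 were higher, by a median of 15.0 points, and all 28 falls were lower. Both sets had the direction of the pooled result in 225 rises and 27 falls. With the set as a term, 45 regions were called (17 higher, 28 lower), 22 of them as before. Adding the depth ratio, 82 were called (39 higher, 43 lower), 52 of them as before. Leaving out 1 library gave 62 calls without right eye 13 dpf replicate 2 and 91 without left eye 13 dpf replicate 3. It gave 130 to 196 without left eye 13 dpf replicate 1, right eye 13 dpf replicate 1, or replicate 2 or 4 of either eye at 44 dpf, and 512 without left eye 13 dpf replicate 2.

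Among regions whose libraries do not overlap, the largest rise was on chromosome 5 from 4338993 to 4339031, from 4.86% ± 10.9 (SD, n = 5) at 13 dpf to 77.1% ± 21.7 (n = 8) at 44 dpf. The region on chromosome 10 from 6875099 to 6875144 rose from 1.64% ± 2.18 to 69.5% ± 33.9. The region on chromosome 11 from 12233764 to 12233828 rose from 1.46% ± 0.821 to 66.1% ± 24.8, with 12.2% ± 7.05 (n = 8) at 21 dpf. Its adjusted p was 0.00033, against 0.00857 to 0.0387 for the other 5 rises named here. On chromosome 20 the region from 13521826 to 13521842 rose from 5.94% ± 13.3 to 67.2% ± 20.4. A pair of regions that were already partly methylated ended near full methylation, the one on chromosome 9 from 1398021 to 1398076 (27.8% ± 25.4 to 89.5% ± 9.33) and the one on chromosome 2 from 24333657 to 24333673 (25.2% ± 15.3 to 84.7% ± 10.1). At 21 dpf the means of these last were between 25.3% and 31.2% in both eyes. In the libraries of set 1, the chromosome 11 region was at 1.39% ± 0.929 (n = 4) at 13 dpf and at 75.3% (95% Wilson interval 70.8 to 79.2) in the single library of 44 dpf. Of these 6 rises, those on chromosomes 11 and 20 kept an adjusted p under 0.05 with the depth ratio as a term, and with the set the 1 on chromosome 11 did (adjusted p of 0.00609 and 0.0347, with 0.000154 to 0.0835 over its 12 alternatives).

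Among the falls whose libraries do not overlap, the largest was on chromosome 15 from 8640253 to 8640298, from 88.9% ± 8.88 (SD, n = 5) at 13 dpf to 48.7% ± 16.3 (n = 8) at 44 dpf. On chromosome 4, from 17423125 to 17423160, methylation fell from 53.7% ± 18.0 to 20.6% ± 5.66. On chromosome 8 the region from 4957611 to 4957644 fell from 97.5% ± 2.91 to 66.8% ± 15.8, and that from 17688853 to 17688962 from 87.6% ± 7.39 to 65.7% ± 7.45. The region on chromosome 3 from 14776716 to 14776748 was nearly fully methylated at 13 dpf (99.6% to 100% in the 5 libraries) and at 73.2% ± 10.5 at 44 dpf. That on chromosome 14 from 13326976 to 13327019 fell from 29.1% ± 3.96 to 13.9% ± 5.85. The adjusted p of the chromosome 3 region was 0.00857, and those of the other 5 were 0.0182 to 0.0418. The regions on chromosomes 3, 4, 14 and 15 kept an adjusted p under 0.05 with the depth ratio as a term, and with the set those on chromosomes 3 and 14 did. The direction of a region is that of its group means, which neither term changes. In the fitted log odds ratio, all 271 rises and 28 falls kept their sign with the depth ratio. With the set, 270 of the 271 rises did.

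**Figure D2:**
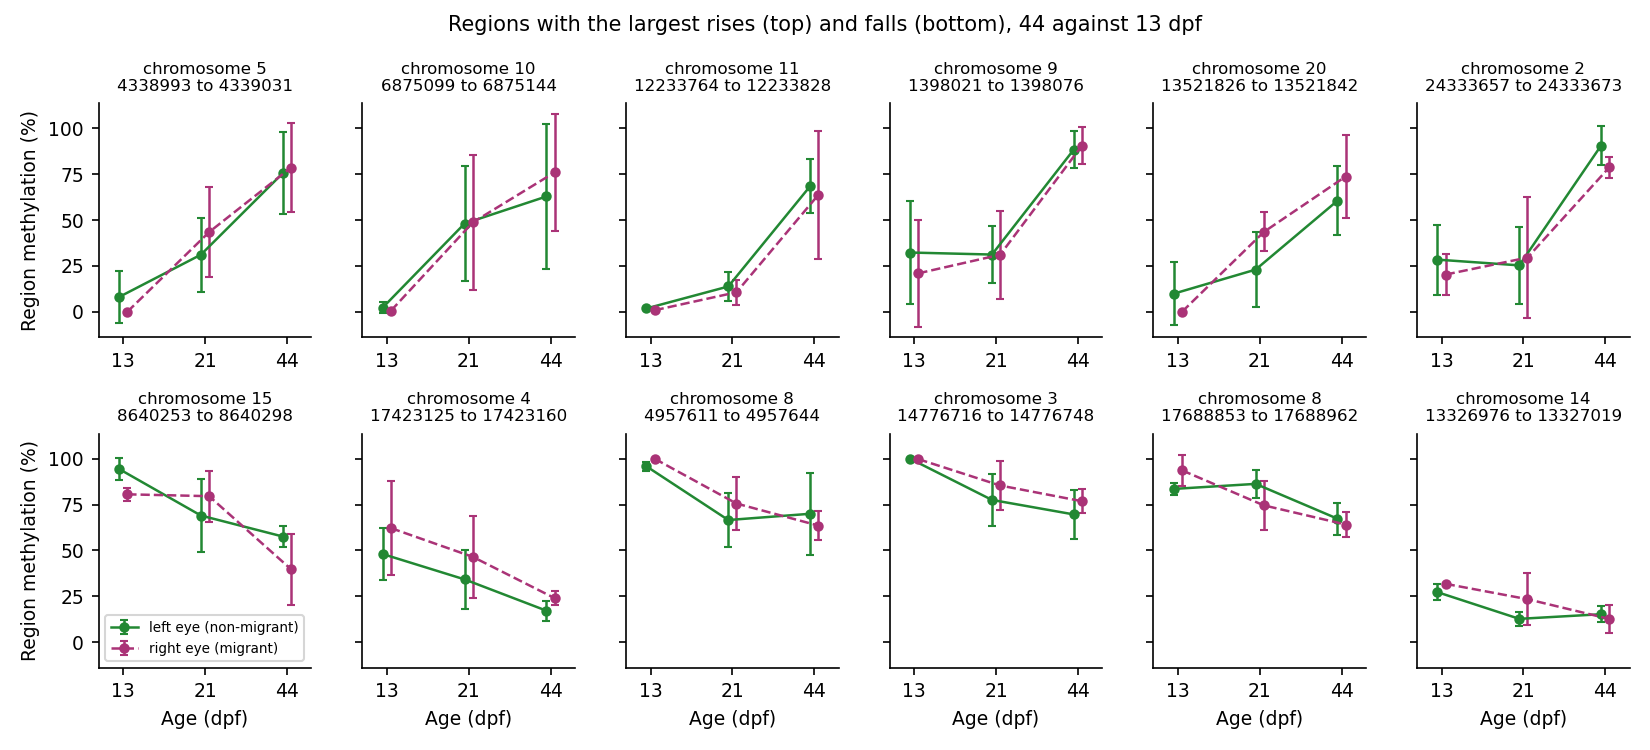
Mean methylation of 12 regions (%, vertical axis) at 13, 21 and 44 dpf (horizontal axis) in the left eye (solid) and right eye (dashed). Points are group means and bars are 1 SD of the libraries of a group (n = 2 to 4). The top panels hold the rises and the bottom panels the falls. The chromosome 11 region stands at 1.86%, 13.8% and 68.5% in the left eye.

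The 299 regions were spread over the genome. Chromosome 13 held the most for the regions tested on it (22, against 13.9 expected, permutation p of 0.0396, adjusted p of 0.64). Expected numbers came from random draws matched on the mean methylation level of the regions, in finer steps than the classes above. Of the 299, 13 had another called region within 10000 bp, against 13.9 expected (one-sided permutation p of 0.598 from 10000 draws).

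Between 13 and 21 dpf, the step from before metamorphosis to its climax, 9 regions were called and all 9 gained methylation. Simulated data with no change gave 0 to 2 calls here (40 draws), but hold no shift shared by a whole library. Of the 6 whose libraries do not overlap between the ages (by chance 0.155% of regions not chosen for a difference), the largest rise was on chromosome 10 from 19182390 to 19182441, from 31.5% ± 12.9 (SD, n = 5) to 70.5% ± 9.89 (n = 8). The regions on chromosome 13 from 17333652 to 17333685 (24.9% ± 10.7 to 58.0% ± 10.9) and on chromosome 9 from 22661771 to 22661821 (8.63% ± 5.13 to 33.8% ± 6.01) followed. Smaller rises were those on chromosome 22 from 3523240 to 3523325 (14.0% ± 5.33 to 33.8% ± 6.91), chromosome 8 from 7688454 to 7688528 (6.55% ± 5.41 to 24.3% ± 6.42) and chromosome 12 from 7763106 to 7763191 (4.35% ± 1.78 to 18.4% ± 4.93). Their adjusted p were 0.0237 to 0.0374, and all 6 were higher at 21 dpf in each eye. At 44 dpf the chromosome 9 region was at 43.6% ± 11.7 (n = 4) in the left eye and 54.6% ± 8.05 (n = 4) in the right, and the chromosome 22 region at 42.3% ± 6.17 and 41.0% ± 10.5. Within set 3, the chromosome 9 region had 11.7% (95% Wilson interval 9.44 to 14.3) in the library of 13 dpf and 34.3% ± 7.84 (n = 5) at 21 dpf. There were 18 calls (6 higher, 12 lower) with the depth ratio as a term, and with the set 11 (2 higher, 9 lower), 1 of them as before. By edgeR 8 were called (4 higher, 4 lower), 0 of them among the 9, and by limma 32 (27 higher, 5 lower), 5 of them among the 9. Leaving out 1 library gave 0 calls (without left eye 21 dpf replicate 1 or right eye 21 dpf replicate 3) to 67 (without left eye 13 dpf replicate 2), and 3 to 18 without right eye replicate 1 or 2 of 13 or 21 dpf or left eye 21 dpf replicate 4.

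Between 21 and 44 dpf, from the climax to the time after it, 1 region was called. It is the region on chromosome 11 from 12233764 to 12233828 named above, which rose from 12.2% ± 7.05 (SD, n = 8) to 66.1% ± 24.8 (n = 8). No library of 21 dpf was above 20.3% and none of 44 dpf was below 24.5%. Its adjusted p was 0.0146, 0.00678 with the depth ratio and 0.0306 with the set. By edgeR and by limma it was 1 and 0.564, and over its 12 alternatives it was 0.00304 to 1. At an unadjusted p under 0.05 there were 1884 regions, and edgeR and limma called 0. With the depth ratio as a term 9 regions were called (7 higher, 2 lower), and with the set 7 (2 higher, 5 lower). Leaving out replicate 1 or 2 of the left eye at 44 dpf, or replicate 2 of the right eye at 21 or 44 dpf, gave 0 calls. Leaving out left eye 44 dpf replicate 3, right eye 44 dpf replicate 1 or right eye 21 dpf replicate 1, 3 or 4 gave 2 or 3.

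Between the migrant and non-migrant eye 18 regions were called at 13 dpf, before migration, 10 of them higher and 8 lower in the right eye. That is no more than simulated data with no difference gave (6 to 31 calls, median 17.5, and 18 or more in 20 of 40 draws), so the count does not show that the eyes differed. Many of the regions were close to fully methylated in one eye. Those named here are regions whose libraries do not overlap between the eyes, as 20% of regions would by chance with 3 and 2 libraries. On chromosome 1 from 8578386 to 8578392 the left eye had 32.9% ± 6.57 (SD, n = 3) and the right eye 99.1% ± 1.22 (n = 2). On chromosome 21 from 14255822 to 14255830 the left eye had 44.0% ± 24.3 and the 2 right eye libraries 99.8% and 100%, and on chromosome 10 from 4411246 to 4411282 they were 67.6% ± 13.8 and 99.7% ± 0.387. The right eye was also higher on chromosome 17 from 4781587 to 4781639 (28.7% ± 8.62 against 89.4% ± 7.08), chromosome 11 from 14764340 to 14764388 (27.3% ± 13.5 against 76.1% ± 8.34) and chromosome 13 from 6041096 to 6041137 (24.8% ± 12.8 against 69.5% ± 9.42). Lower in the right eye were the regions on chromosome 21 from 8501932 to 8501976 (93.7% ± 5.82 against 21.1% ± 29.8), chromosome 14 from 15178103 to 15178195 (99.1% ± 1.53 against 34.2% ± 15.5) and chromosome 22 from 3361542 to 3361587 (97.6% ± 4.15 against 51.6% ± 12.6). Smaller falls were on chromosome 8 from 23571440 to 23571456, chromosome 2 from 25104206 to 25104242 and chromosome 18 from 1676327 to 1676421, with differences of -28.5, -21.9 and -11.5 points.

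The adjusted p of these 12 regions were 0.00612 to 0.0491, the lowest for chromosome 14. Of the 12, 9 kept an adjusted p under 0.05 with the depth ratio as a term, with the set 11, and with each of the 2 terms 8. By edgeR 2 did, those on chromosome 14 and chromosome 21 from 14255822 (adjusted p of 0.0303 and 0.0258, with 0.000675 to 0.755 and 0.000371 to 0.77 over their 13 alternatives). At 21 dpf the chromosome 14 region had 82.7% ± 9.92 (SD, n = 4) in the left and 67.9% ± 9.48 (n = 4) in the right eye, and at 44 dpf 75.4% ± 11.0 and 81.1% ± 2.61. The 2 right eye libraries of 13 dpf were both of set 1. With the depth ratio as a term 43 regions were called (17 higher, 26 lower), and with the set 82 (69 higher, 13 lower). By edgeR 7 were called and by limma 20, of which 2 and 5 were among the 18. Without left eye replicate 3 there were 14, without left eye replicate 2 there were 52, and without right eye replicate 1 or replicate 2 there were 63. When the dispersion came from the 5 libraries of 13 dpf alone, 0 were called.

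At 21 dpf, the climax, no region was called between the eyes with the groups alone. At an unadjusted p under 0.05 there were 2101 regions, and edgeR and limma called 0. The 3 of lowest p had an adjusted p of 0.105, and of 0.00113 to 1 over their alternatives. On chromosome 19 from 4720119 to 4720235 the right eye had 4.53% ± 3.45 (SD, n = 4) and the left 0.0266% ± 0.0532 (n = 4). On chromosome 11 from 13149178 to 13149301 the values were 5.86% ± 3.48 and 0.0791% ± 0.158. On chromosome 22 from 10085841 to 10085966 the left eye had 3.39% ± 2.62, and the right eye had no methylated read. At 13 and 44 dpf the group means of these 3 regions were at most 0.184%. Adding the depth ratio, 2 regions were called and with the set 3, and 1 without right eye replicate 2 or replicate 4. The replicate number as a block gave 39 calls, and library numbers 11 apart as a block gave 43. Whether these numbers pair the samples stays open.

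After migration, at 44 dpf, no region was called between the eyes with the groups alone either. An adjusted p under 0.05 was reached by 3 regions whose difference was under 10 points, 2026 had an unadjusted p under 0.05, and edgeR and limma called 0. On chromosome 22 from 11422528 to 11422545 the right eye had 7.1% ± 8.26 (SD, n = 4), and no methylated read was seen in the other 5 groups. On chromosome 4 from 10385777 to 10385815 the right eye had 7.79% ± 15.4 and the left none. On chromosome 16 from 13760268 to 13760290 the left eye had 2.62% ± 3.02 and the right 0.0552% ± 0.11. With the set as a term, by edgeR and by limma, the adjusted p of these 3 was 0.562 or more. With the depth ratio it was 6.86e-05 for the region on chromosome 22 and 1 for the other two, and over their alternatives it was 6.86e-05 to 1. There were 9 calls with the depth ratio as a term and 1 with the set. Without right eye replicate 2, 3 or 4 there were 2, 3 and 8. The replicate number as a block gave 31 calls (27 higher, 4 lower in the right eye). The block by library number gave 34 (29 higher, 5 lower). Whether these numbers pair the samples stays open, and so does a difference between the eyes at this age.

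Stage changes within 1 eye were then compared between the eyes. In the left eye 1 region was called between 13 and 21 dpf (chromosome 22 from 3523240 to 3523325, 14.0% to 36.5%) and 0 between 21 and 44 dpf. In the right eye 9 were called between 13 and 21 dpf, 5 higher and 4 lower, and 0 between 21 and 44 dpf. Simulated data with no change gave 0 to 10 calls in the left and 2 to 20 in the right eye between 13 and 21 dpf (medians 2 and 8.5), so these counts do not show a change. Among these 9, chosen here after their values were seen, the region on chromosome 15 from 17491767 to 17491862 was at 43.9% at 13 dpf and 90.4% at 21 dpf, and the left eye was at 80.4% and 78.1%. The region on chromosome 10 from 25142119 to 25142165 went from 13.4% to 56.3% in the right eye and from 31.2% to 46.9% in the left. The region on chromosome 21 from 14255822 to 14255830, named above at 13 dpf, went from 99.8% and 100% in the 2 libraries to a mean of 31.6% in the right eye. The difference between the eyes' stage changes was itself tested at each step. No region was called for the step from 13 to 21 dpf, where 1658 had an unadjusted p under 0.05. The same held for the step from 21 to 44 dpf, with 1270 such regions. By edgeR 2 and 0 were called, and by limma 10 and 0. For the 2 steps within 1 eye from 21 to 44 dpf, 2267 and 2221 regions had an unadjusted p under 0.05, in the left and right eye, and edgeR and limma called 0 in both. There were 9 and 10 calls with the depth ratio as a term, and with the set 2 and 62.

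The counts within 1 eye moved with single libraries. From 13 to 21 dpf in the left eye there were 13, 102 and 9 calls without replicate 1, 2 and 3 of 13 dpf, and 0, 2 and 0 without replicate 1, 2 and 3 of 21 dpf. By edgeR there were 0 and by limma 2, with the depth ratio 14 (1 higher, 13 lower) and with the set 12 (4 higher, 8 lower). In the right eye there were 70 and 44 without replicate 1 and 2 of 13 dpf, and 1, 3 and 4 without replicate 2, 3 and 4 of 21 dpf. By edgeR there were 14 and by limma 28 (1 and 3 of them among the 9), with the depth ratio 48 (17 higher, 31 lower) and with the set 40 (2 higher, 38 lower). From 21 to 44 dpf the left eye had 1 call without replicate 3 of 21 dpf or replicate 1 of 44 dpf. The right eye had 1 without replicate 4 of 21 dpf, and 2, 4 and 11 without replicate 2, 3 and 4 of 44 dpf. The difference between the eyes' steps from 13 to 21 dpf had 7 calls without right eye 13 dpf replicate 1, and 1 without right eye 13 dpf replicate 2 or left eye 21 dpf replicate 2.

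**Figure D3:**
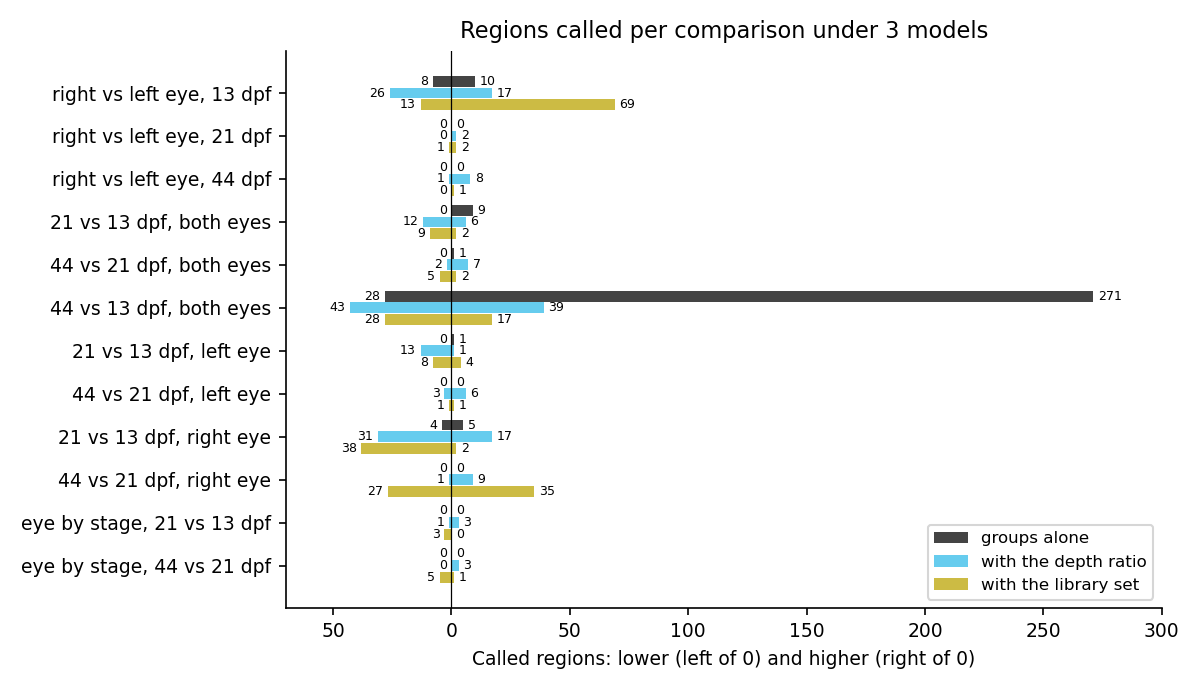
Number of regions called per comparison (horizontal axis), lower to the left of 0 and higher to the right, with the groups alone, with the depth ratio and with the library set as a further term. Directions are those of the group means in every model. The comparison of 44 with 13 dpf has 271 higher and 28 lower regions with the groups alone, 39 and 43 with the depth ratio, and 17 and 28 with the library set.

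Over whole libraries, the mean methylation of all CpGs used was 19.4% ± 2.56 (SD, n = 5) at 13 dpf, 21.4% ± 2.03 (n = 8) at 21 dpf and 22.1% ± 2.04 (n = 8) at 44 dpf. No difference passed the adjusted threshold with the groups alone. The 44 dpf libraries were 2.72 points above those of 13 dpf (exact permutation p = 0.0495, adjusted p = 0.297). The steps of 1.96 and 0.76 points had p of 0.17 and 0.499 by the same test. CpGs of 10 to 80% were at 37.8% ± 9.07, 45% ± 7.34 and 47.7% ± 7.37 (9.92 points from 13 to 44 dpf, adjusted p of 0.297), and those of 80% or more at 88.2% ± 3.33, 89.1% ± 1.84 and 89.0% ± 1.76. Within set 1 the mean was 18.8% ± 2.43 (n = 4) at 13 dpf, 17.1% (n = 1) at 21 dpf and 19.1% (n = 1) at 44 dpf. Within set 3 it was 22.0% (n = 1), 21.4% ± 0.643 (n = 5) and 21.0% ± 3.27 (n = 2). The direction of the difference between 44 and 13 dpf turned with the depth ratio taken out (-0.592 points) and with the set taken out (-0.949 points). The step from 13 to 21 dpf turned too (-0.851 and -0.994 points), and with the depth ratio taken out it passed (adjusted p of 0.0457, with 0.0457 to 0.8 over its 8 alternatives). The p of 0.0457 can be too low, since the slope of the ratio was not fitted anew for each permutation. No difference between the eyes passed the test. The right eye minus the left was 1.01 points at 13 dpf (exact permutation p = 0.8, where 0.1 is the smallest possible), 0.16 points at 21 dpf (p = 0.971) and 2.08 points at 44 dpf (p = 0.229). It was -0.648 and -0.565 points at 13 dpf without left eye replicate 3 and right eye replicate 1. At 21 dpf it was -0.0719, -0.506 and -0.533 points without left eye replicate 2 and right eye replicates 1 and 3.

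The CpGs under 10% methylation gained over the same ages. Their mean was 0.595% ± 0.118 (SD, n = 5) at 13 dpf, 0.846% ± 0.181 (n = 8) at 21 dpf and 1.07% ± 0.203 (n = 8) at 44 dpf. The 0.476 points between 13 and 44 dpf had an exact permutation p of 0.00381 and an adjusted p of 0.0229. Stage labels were permuted in each eye separately, so this p can be too low if left and right eye libraries come from the same fish. The steps of 0.251 and 0.224 points had an adjusted p of 0.0661 each. The difference between 13 and 44 dpf passed in the 3 classes of CpGs from 1 to 10%. Those of 2 to 5% went from 2.01% ± 0.334 through 3.01% ± 1.51 to 3.95% ± 1.40, and those of 5 to 10% from 4.12% ± 1.31 through 6.80% ± 2.36 to 9.68% ± 3.08 (adjusted exact permutation p = 0.00952 for both). Those of 1 to 2% went from 1.16% ± 0.188 to 1.57% ± 0.188, with the same adjusted p. CpGs under 0.5% were at 0.0822% ± 0.0398 and 0.124% ± 0.0552, and those of 0.5 to 1% at 0.615% ± 0.191 and 0.78% ± 0.237. Their differences of 0.042 and 0.165 points did not pass (adjusted p of 0.219 and 0.23 by the same test).

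Within set 1 the CpGs under 10% were at 0.548% ± 0.0629 (n = 4) at 13 dpf, 0.545% (n = 1) at 21 dpf and 0.768% (n = 1) at 44 dpf. Within set 3 they were at 0.782% (n = 1), 0.815% ± 0.0439 (n = 5) and 1.03% ± 0.306 (n = 2). The difference between 44 and 13 dpf was 0.258 points with the depth ratio taken out (adjusted p = 0.0233) and 0.189 points with the set taken out (adjusted p = 0.0571, both by permutation of the values left). Both p can be too low, since neither term was fitted anew for each permutation. Over the 8 alternatives of this difference other than single libraries left out, the adjusted p was 0.0229 to 0.234. The last was in a setting where no p under 0.0625 is possible. Its adjusted p also rose above 0.05, to between 0.0514 and 0.0661, without left eye 13 dpf replicate 1 or 3, right eye 13 dpf replicate 1 or 2, or right eye 44 dpf replicate 4, where the difference was 0.452 to 0.487 points. The adjusted p of the step from 13 to 21 dpf fell to 0.0343 and 0.0171 without right eye 13 dpf replicate 1 and right eye 21 dpf replicate 2 (0.263 and 0.294 points). That of the step from 21 to 44 dpf fell to 0.038, 0.0495 and 0.0318 without left eye 44 dpf replicates 1 and 3 and right eye 21 dpf replicate 3 (0.268, 0.261 and 0.272 points).

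**Figure D4:**
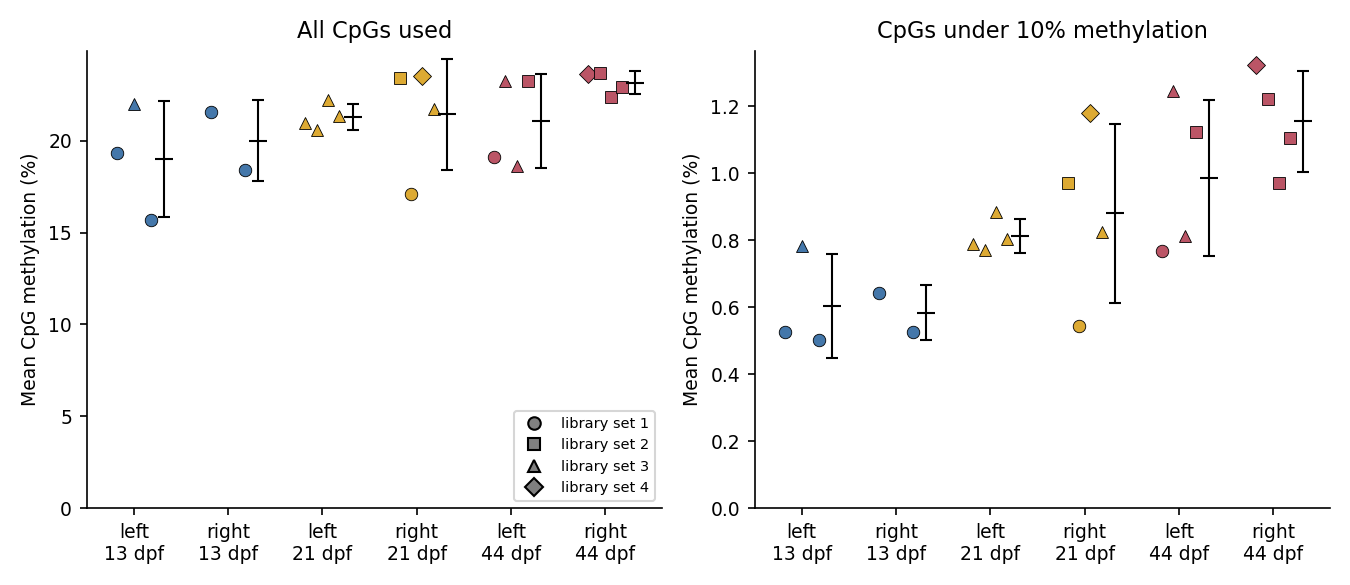
Mean CpG methylation (%, vertical axes) of each library by eye and age (horizontal axes), for all CpGs used and for CpGs under 10%, with the library set as symbol. Black bars are group means with 1 SD (n = 2 to 4). The 13 dpf libraries lie between 0.502% and 0.782% for the CpGs under 10%, and those of 44 dpf between 0.768% and 1.32%.

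**Figure D5:**
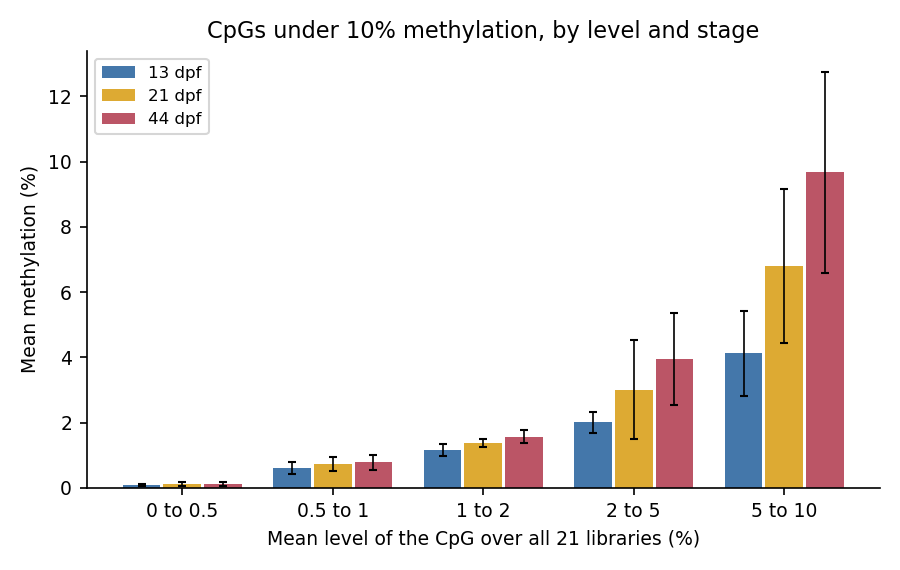
Mean methylation (%, vertical axis) at 13, 21 and 44 dpf of CpGs under 10%, in 5 classes of their mean level over all 21 libraries (horizontal axis). Bars are means over libraries with 1 SD (n = 5, 8 and 8), and the CpGs of 5 to 10% stand at 4.12%, 6.80% and 9.68%.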

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

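The tests of the non-CpG pattern in this part were set down before their results were seen. Each group of 4 to 10 libraries was searched for a library far from the others by Dixon's test, in 28 groups of library values and 47 groups of region values. It singled out a library in 5 and in 9 of them. Chance gives about 1 in 20 groups for normal values without ties, which does not hold here. In several of the region groups all other libraries were tied at 0 or 100%, where any other value is singled out. Groups of an eye at a stage and of the whole stage also share libraries. These counts are therefore not set against chance.

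Right eye 44 dpf replicate 1 and right eye 21 dpf replicate 3 had far more methylated reads at CHG and CHH cytosines than the other libraries. The first had 1.12% (95% Wilson interval 1.12 to 1.13), where the others of its group had 0.278 to 0.312% and the other 44 dpf libraries 0.245 to 0.378%. The second had 1.11% (1.11 to 1.11), where the other 21 dpf libraries had 0.201 to 0.436%. Left eye 13 dpf replicate 2 had 0.397% (0.397 to 0.398), where the other 13 dpf libraries had 0.2 to 0.226%. All 21 libraries held some such calls, at 0.2% or more. The calls are at cytosines other than the CpGs compared in the report, but the reads that hold them can cover those CpGs too. The CpG values of these libraries can therefore be raised as well.

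For the 2 libraries near 1%, whole reads that escaped conversion were weighed against conversion that was incomplete throughout. In these 2, 64.0 and 67.1% of methylated non-CpG reads lay at cytosines methylated at 50% or more, against 20.1 to 46.0% in the other libraries, and 83.6 and 84.0% of the cytosines near such a cytosine were also at 50% or more, against 13.8 to 65.9%. That is what reads that kept nearly all their cytosines would give, and few of these cytosines were shared (639 of 25612, or 2.49%). Incomplete conversion throughout stays open, since CpGs under 0.5% stood 0.589 and 0.57 points above the other libraries of their groups, less than the non-CpG excess of 0.831 and 0.795 points. No biological explanation was tested.

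Right eye 21 dpf replicate 2 had a mean CpG methylation of 17.1%, against 20.6 to 23.5% in the other 7 libraries of 21 dpf. Left eye 13 dpf replicate 2 stood apart in 2 regions that rose by 44 dpf. On chromosome 5 from 4338993 to 4339031 it had 24.3% (95% Wilson interval 20.1 to 29.1), and on chromosome 20 from 13521826 to 13521842 it had 29.7% (24.6 to 35.4), where the other 4 libraries of 13 dpf had no methylated read (3 counts would be at most 1.7 and 2.86%). Right eye 13 dpf replicate 2 had 0% (0 to 0.591) on chromosome 11 from 12233764 to 12233828, against 1.72 to 1.95% in the others. It also had 99.6% (lower limit 98.5) on chromosome 3 from 14776716 to 14776748, against 100%. Since a read counts once for each CpG it covers, these intervals are too narrow. Whether these 2 values stand apart stays open.

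Right eye 44 dpf replicate 1 had 11.2% (95% Wilson interval 8.85 to 14.1) on chromosome 15 from 8640253 to 8640298, against 45.7 to 63.8% in the other 7 libraries of 44 dpf. On chromosome 4 from 10385777 to 10385815 it had 30.8% (28.1 to 33.7), against 0 to 0.323% in the other right eye libraries, so that the mean of 7.79% there rests on this library. In 3 more regions, 1 library was above 0 by a very small share and the other 3 of its group held no methylated read. These were left eye 21 dpf replicate 2 on chromosome 19 from 4720119 to 4720235 (0.106%, 0.0188 to 0.6), left eye 21 dpf replicate 3 on chromosome 11 from 13149178 to 13149301 (0.316%, 0.0559 to 1.77) and right eye 44 dpf replicate 3 on chromosome 16 from 13760268 to 13760290 (0.221%, 0.039 to 1.24). In the 3 groups, 3 counts in a library at 0 would be at most 0.369, 1.32 and 3.8%.

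On chromosome 7 from 15333502 to 15333649 the change from 13 to 21 dpf differed between the eyes by less than the 10 points needed for a call. The left eye had 0.0103% at 13 dpf and 0.422% at 21 dpf, and the right eye 2.09% and 0.0262%. The difference between these changes was -2.47 points (quasi-binomial F test, adjusted p of 0.0153).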

How the results depend on the processing

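The depth ratio, the library set, limma, the rule of 2 libraries per group and leaving out the 2 libraries of high non-CpG methylation were chosen after seeing the data. The planned tests of gene lists and genomic features were not run, since no region was placed on a gene. The cause was not tested for any change below, unless the setting itself gives it.

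All 37 named results kept their direction, where they could be tested, when the CpGs or libraries used were changed. With a further term, a block, edgeR, limma or the compared groups alone, the direction comes from the same group means. It could not change there. Of the 31 that were called, 31 kept their side of the threshold with no variant filter and 27 with 5 reads, and the 23 that could be tested with 20 reads did. The number was 19 with the depth ratio, 16 with the set, 16 with limma and 5 with edgeR. The other 6, of the eyes at 21 and 44 dpf, differ by under 10 points and say little here.

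With the share of methylated reads in place of the mean over CpGs, the differences were 6.97, 2.2 and 9.17 points for 21 minus 13, 44 minus 21 and 44 minus 13 dpf and 2.23, 1.13 and 5.51 points for the eyes at 13, 21 and 44 dpf, larger in all 6, and none passed (adjusted p of 0.149 to 0.829).

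With 20 reads the counts became 5 for 44 against 21 dpf, and 3 and 14 for 21 against 13 dpf in the left and right eye. With 5 reads they became 16 for the right eye step and 1 for the difference between the eyes' steps from 13 to 21 dpf. With 2 libraries per group, which tests more regions, there were 3 for the eyes at 13 dpf, 4 for 21 against 13 dpf, and 0 and 1 for this step in the left and right eye. A difference of 25 points left 11 for the eyes at 13 dpf, 151 for 44 against 13 dpf, and 0 and 5 for 21 against 13 dpf in the left and right eye. It is a stricter rule by construction.

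By edgeR there were 7 for the eyes at 13 dpf, 29 for 44 against 13 dpf, 0 for 44 against 21 dpf, 0 and 14 for 21 against 13 dpf in the left and right eye, and 2 for the difference between the eyes in this step. By limma there were 32 for 21 against 13 dpf, 0 for 44 against 21 dpf, 188 for 44 against 13 dpf, 2 and 28 in the left and right eye and 10 for the difference. With the depth ratio in limma there were 16 for 44 against 13 dpf, 0 and 45 in the left and right eye and 13 for the difference. With the libraries of the compared groups alone there were 0 for the eyes at 13 dpf, 1 for 21 against 13 dpf, 0 for 44 against 21 dpf, 150 for 44 against 13 dpf and 0 in each eye from 13 to 21 dpf.

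Single CpGs gave 732, 10 and 15 for the eyes at 13, 21 and 44 dpf, and 2 for 21 against 13 dpf. Of the 732, 629 were higher and 103 lower in the right eye, a less even split than that of the regions. They gave 104 and 25 for the left eye steps, 572 and 11 for the right eye steps, and 3 for the difference between the eyes from 13 to 21 dpf. Of the 572, from 13 to 21 dpf, 118 were higher and 454 lower. Without the 2 libraries of high non-CpG methylation there were 4 for 21 against 13 dpf, 2 for 44 against 21 dpf and 3 for the right eye from 13 to 21 dpf, and the right minus left mean at 21 dpf was -0.533 points.

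With the depth ratio there were 43, 2 and 9 for the eyes at 13, 21 and 44 dpf, and 18, 9 and 82 for 21 against 13, 44 against 21 and 44 against 13 dpf. Within the left eye there were 14 and 9, within the right eye 48 and 10, and 4 and 3 for the difference between the eyes in each step. The mean over CpGs turned to -0.851 points for 21 minus 13 dpf (which passed the threshold, adjusted p of 0.0457), -0.592 for 44 minus 13 dpf and -0.377 for the eyes at 13 dpf. CpGs under 10% passed the threshold from 21 to 44 dpf (0.192 points). The p-values of these library values can be too low, since the slope was not fitted anew for each permutation.

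With the library set there were 82, 3 and 1 for the eyes, 7 for 44 against 21 dpf, 45 for 44 against 13 dpf, 12 and 2 within the left eye, 40 and 62 within the right eye, and 3 and 6 for the difference between the eyes. The mean over CpGs turned to -0.994 points for 21 minus 13 dpf and -0.949 for 44 minus 13 dpf, and to -0.0171 and -0.358 for the eyes at 21 and 44 dpf. CpGs under 10% passed from 21 to 44 dpf (0.18 points) and no longer passed from 13 to 44 dpf (0.189 points). The p-values of these library values can be too low in the same way.

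The replicate numbers were checked for pairing by how the left and right library of a number deviate together from their groups. The mean correlation of the pairs was -0.058 (-0.136 to 0.0199) at 13 dpf, 0.0494 (-0.0137 to 0.0977) at 21 dpf and 0.11 (0.0371 to 0.144) at 44 dpf, where all 8 libraries correlated best with their own number. Not every pair was over 0.1, as the rule set before asks, so the number was not taken to pair the samples. The match at 44 dpf and the C/T variants shared by library numbers 11 apart (at 21 and 44 dpf the same pairs) leave it open whether they are pairs. With this number as a block there were 95, 39 and 31 for the eyes, 18, 19 and 171 for the stages, 41 and 14 within the left eye, 33 and 86 within the right eye, and 7 and 21 for the difference between the eyes. The right minus left mean at 13 dpf was -0.648 points, and the rise of CpGs under 10% from 13 to 44 dpf had 0.478 points, where the smallest possible p of 0.0625 cannot pass. With library numbers 11 apart as a block there were 189, 43 and 34 for the eyes.

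Leaving out 1 library in turn gave 14 to 63, 0 to 1 and 0 to 8 regions for the eyes at 13, 21 and 44 dpf, and 0 to 67, 0 to 3 and 62 to 512 for 21 against 13, 44 against 21 and 44 against 13 dpf. It gave 0 to 102 and 0 to 1 for the left eye steps, 1 to 70 and 0 to 11 for the right eye steps, and 0 to 7 and 0 for the difference between the eyes. The libraries behind these ranges are named with each comparison. Where a group kept 1 library, it is assumed to vary like the other groups. The mean over CpGs ranged from 1.03 to 2.61, 0.149 to 1.26 and 1.79 to 3.37 points for 21 minus 13, 44 minus 21 and 44 minus 13 dpf, and from -0.648 to 2.58, -0.533 to 1.61 and 1.27 to 2.82 points for the eyes. CpGs under 10% ranged from 0.203 to 0.298, 0.181 to 0.272 and 0.44 to 0.522 points for the stages. Besides the lowest, the eye difference turned to -0.565 points at 13 dpf without right eye replicate 1, and to -0.0719 and -0.506 points at 21 dpf without left eye replicate 2 and right eye replicate 1.

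Depth limits the single values, since a CpG at the minimum of 10 reads has a 95% Wilson interval of up to 26.3 points on either side. A region at the median count of 530 has one of 4.24 points. That interval is too narrow, since a read counts once for each CpG of the region it covers.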

Other observations

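The tests of the depth ratio, the conversion and the library set against the regions called between 13 and 44 dpf, that of the set against the CpGs under 10%, that of library numbers 11 apart and the exchange of labels by such pairs were chosen after the result was seen. The other tests of this part were set down before.

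Of the 299 regions called between 13 and 44 dpf, 20 were also called with the depth ratio and with the library set as a term, 14 of them higher and 6 lower at 44 dpf. The region on chromosome 8 from 13289458 to 13289482 was at 11.0% ± 7.10 (SD, n = 5), 42.7% ± 13.6 (n = 8) and 66.2% ± 16.9 (n = 8) at 13, 21 and 44 dpf. That on chromosome 16 from 3238385 to 3238418 was at 6.79% ± 8.22, 22.1% ± 15.8 and 51.4% ± 8.91, and that on chromosome 13 from 3500800 to 3500990 at 25.6% ± 10.7, 43.6% ± 7.98 and 59.9% ± 10.3. Low levels rose on chromosome 22 from 5471574 to 5471681 (2.82% ± 2.5, 10.5% ± 5.29 and 22.9% ± 3.72), chromosome 17 from 15271549 to 15271580 (1.01% ± 2.09, 11.0% ± 4.68 and 24.9% ± 9.35) and chromosome 13 from 4833062 to 4833244 (4.54% ± 2.45, 8.35% ± 3.2 and 23.5% ± 5.67). Falls were those on chromosome 6 from 19131423 to 19131502 (44.4% ± 14.4, 25.1% ± 11.6 and 15.1% ± 7.74) and chromosome 12 from 17070906 to 17070953 (57.7% ± 5.29, 46.9% ± 6.64 and 41.0% ± 9.46).

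Whether the 2 eyes changed alike with stage was tested over the 6568 regions of 10 to 80% methylation. With stage labels exchanged in each eye apart, the changes from 13 to 44 dpf correlated between left and right eye with a Pearson r of 0.297 (Spearman rho 0.308, one-sided exact permutation p of 0.0019, the smallest possible, adjusted p of 0.0114), and those from 21 to 44 dpf with 0.217 (rho 0.181, adjusted p of 0.0159). These were 0.194 and 0.214 with the depth ratio taken out, and with the set 0.136 and 0.167. From 13 to 21 dpf the r of 0.0959 (rho 0.106) did not pass (adjusted p of 0.163). If library numbers 11 apart are 1 fish, its left and right eye raise these values without a change with stage. With labels exchanged by such pairs, 21 to 44 dpf did not pass (exact permutation p of 0.0857, 70 exchanges), and the p of 0.0667 for 13 to 44 dpf is the smallest that 15 exchanges give, so a shared change stays open. Taken from different pairs, with fewer libraries in each mean, the r was 0.0812 and 0.14. A difference between the eyes that recurs at another stage stays open for all 3 pairs of stages. The r was -0.0431 (rho -0.0447) for 13 against 21 dpf, 0.109 (rho 0.103) for 21 against 44 dpf and 0.00239 (rho 0.0128) for 13 against 44 dpf, with adjusted p of 0.741, 0.155 and 0.567, and the first lies within the spread of exchanged labels (5% and 95% points -0.112 and 0.112). These correlations are across regions of the same libraries, which are not independent replicates (library labels were permuted).

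Most regions called between 13 and 44 dpf were higher at 44 dpf (90.6%). Incomplete conversion is argued against, since the non-CpG level differed by 0.164 points (upper bound 0.505) where CpGs of 10 to 80% differed by 9.92 points. The depth ratio stays open for the direction, since its slope within groups predicts 11.9 points (10.7 to 13.2). With it as a term, 47.6% (36.4 to 58.9) of the called regions were higher by their group means. That share reflects which regions were called, not the direction in the fit, where all 271 rises kept their sign. The library set stays open too (-3.48 points with it as a term, exact permutation p of 0.303). For 52 of the 299 calls the depth ratio is argued against as the whole cause, since they were called with it as a term as well. All 38 rises and 14 falls among them kept the sign of their log odds ratio in that fit. By limma with the depth ratio, however, 16 regions were called (6 higher, 10 lower) and 10 of them were among the 299. The ratio therefore stays open for the other rises. The set cannot be told apart, since 22 were called with it and 4 of the 5 libraries of 13 dpf are in 1 set. Whether calls ended by a smaller change or by lower precision was not separated, and a change with age itself remains open. The median log2 odds ratio of the 271 rises was 2.84 (quartiles 2.2 to 4.27) before. It was 2.07 (1.40 to 3.45) with the ratio and 2.05 (1.25 to 3.38) with the set, where 271 and 270 kept their sign. For the falls it was -2.36 (quartiles -13.9 to -1.55) before and -2.72 (-14.2 to -1.53) with the ratio. The size was larger with the ratio in 21 of 28 falls and in 8 of the 14 no longer called. Some regions had a group of 13 dpf with every read, or none, methylated. No finite odds ratio exists there and the fit stops at its limit. The lower quartiles of the falls and the counts of larger sizes therefore say little.

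The rise of CpGs under 10% from 13 to 44 dpf was weighed in the same way. With the depth ratio taken out 0.258 of 0.476 points were left (permutation p of 0.00571, which can be too low since the slope was kept fixed). With the non-CpG level of each library subtracted 0.311 points were left (exact permutation p of 0.0324). By the rule set before, which used unadjusted p, this argues against each as the whole cause. The library set was judged by an adjusted p as well, so these explanations were not held to the same standard. Within library sets the rise was 0.119 points per stage (permutation within sets, p of 0.00478), against 0.237 over all libraries, but with the set taken out 0.189 of the 0.476 points were left and did not pass (adjusted p of 0.0571, with 0.0229 to 0.234 over its 8 alternatives, the last where no p under 0.0625 is possible), so the set as the whole cause stays open. A part in the rise stays open for the depth ratio and the conversion, as does a change with age. The p-values of this rise take left and right eye libraries as independent, which was not established.

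Splits of the same libraries tested chance in how they were grouped, in the 9 comparisons that have 3 or more libraries on each side. For 44 against 13 dpf, 1 of the 100 splits drawn out of 525, the real one, reached the count of 299 (highest other drawn 3). For 21 against 13 dpf it was 1 of 100 as well (9 regions, highest other 4), but edgeR called 0 of these 9, the groups compared only gave 1 call, not among the 9, and there were 0 without left eye 21 dpf replicate 1 or right eye 21 dpf replicate 3. For 44 against 21 dpf 4 of 100 reached the real count of 1 and the highest other was 2, with a count of 0 by edgeR and limma, and 0 without left eye 44 dpf replicate 1 or 2 or replicate 2 of the right eye at 21 or 44 dpf. With 9 comparisons tested, this leaves chance open for both. A split that follows the library sets, which moves 2 libraries and was not among those drawn, called 343 regions (334 higher), more than the ages did, so the libraries have a structure of their own, and the values within sets are those given with this comparison. Chance cannot be excluded for 21 against 13 dpf in the left eye (1, highest other 6; 14 of 35 splits). The comparisons where 0 were called cannot be judged in this way, since every split reaches that count. These are the eyes at 21 dpf (highest other 0; 35 of 35) and 44 dpf (9; 35 of 35), 44 against 21 dpf in the left eye (1; 35 of 35) and in the right eye (1; 35 of 35), and the eyes' steps from 21 to 44 dpf (2; 100 of 100).

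Libraries of the left and right eye whose library numbers lie 11 apart share C/T variants more than other pairs. Over 403 variants, the mean correlation of the 10 pairs was 0.181 (-0.101 to 0.434, 7 pairs over 0.1), against 0.0294 over the 3456 possible pairings (one-sided exact permutation p of 0.0101). A candidate explanation is that such a pair is the left and right eye of 1 fish, which the labels do not state.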
